A study of Homo sapiens with 2 samples.

How the data were processed

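p53 ChIP-seq was measured in GM12878 lymphoblastoid cells treated with 10 µM nutlin-3 for 18 hours, with 1 ChIP library and 1 input library. Per the labels' protocols, p53-bound DNA was isolated from sonicated nuclei with a mouse monoclonal antibody, amplified for 15 PCR cycles, size-selected at about 250 bp including adaptors, and sequenced on a Genome Analyzer II. The submitters' processing notes name CASAVA 1.4, BWA and the builds hg18 and hg19 without saying what each was used for. The deposited table is a narrowPeak list on hg19, per the file header, and its file name carries the name of the peak caller QuEST. How the input entered the calling, the thresholds, and how the list was reduced to the regions deposited are not given in the sources used here.

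The enrichment values in the narrowPeak signal column were deposited by the authors as a ratio per region; what the ratio is relative to is not given in the sources used here. The −log10 p and −log10 q values per region were deposited by the authors as the peak caller gave them. The score column deposited by the authors holds 1000 in every region and was not used further. The remaining columns give the region's position and the offset of its summit. Starts were converted to 1-based positions. The list belongs to 1 ChIP library, so no region has a replicate, and it carries no read totals, so depth is unknown and no interval for an enrichment can be given. PCR reads without molecular identifiers are not independent molecules. Intervals of shares and densities cover counting error only, and those of medians and ratios cover the spread between regions of this list; none covers differences between experiments.

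Before the data were examined, the rule was set to name the 15 regions of highest enrichment, to describe the list and its density per chromosome, to repeat the description for only the regions of higher enrichment and with summits within 200 bp merged, and to test p53 motifs, genomic context and 10 gene lists at the regions. The motif, context and gene list tests, and the gene names that the rule asked for, need hg19 sequence or annotation, which were not used here. The gene table at hand is on another build, GRCh38, so no coordinate was taken from it and no gene was assigned to a region. Regions are therefore given by their names and hg19 coordinates. The test between chromosomes and the cluster, neighbour and numbering comparisons were chosen after the list was seen.

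Clusters were runs of at least 3 summits with neighbours within 100 kb. The number of regions in clusters was compared with 10000 random placements, in which each chromosome's regions were drawn evenly between its first and last summit. Clusters and other regions were compared by the mean log10 of enrichment, −log10 q, width and the upper limit over enrichment, each cluster being 1 value, with a two-sided permutation test of 100000 resamples, Benjamini-Hochberg adjustment over the 4 measures, and bootstrap intervals from 10000 draws of loci. Regions per chromosome were tested with a Monte Carlo chi-square test of 100000 draws against the spanned length, counting 1 region fewer per chromosome because 2 summits define the span. Density intervals are exact Poisson intervals, shares have exact Clopper-Pearson 95% intervals, and medians have binomial order-statistic intervals. Chromosome and cluster comparisons used the autosomes and X only, which leaves out 24 of the 1183 regions. These are the mitochondrial region R-7 and the regions called on the Y chromosome. The description of the whole list, the correlations over all regions and the numbering comparisons keep them. The upper limit of a region's enrichment is the highest enrichment of that region and all regions with a higher number.

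The functions were tested on simulated lists of 1159 regions. All regions (100%) of 20 planted clusters of 5 were found, as they had to be, since each was planted well inside the cluster distance. A planted enrichment ratio of 0.5 came out as 0.532. A planted step of 0.0825 was recovered as 0.0825. Of 100 lists with no difference, 1 had a permutation p under 0.05. Region counts were also drawn 100 times in proportion to the chromosome spans, without placing regions, and 8 draws had a chromosome p under 0.05. These draws follow the null of that test, so they check its calculation only. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives tried were the 591 regions of higher enrichment (579 on the autosomes and X), the 579 with the higher −log10 q, merging of summits within 200 bp, and for pairs within 1000 bp, other cluster distances and sizes, counting each cluster once, and leaving out the largest cluster. Regions with equal enrichment at the cut were divided by their number.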

Results

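The data were p53 chromatin immunoprecipitation sequencing (ChIP-seq) regions from GM12878, an established human B-lymphoblastoid cell line. The cells had been exposed to 10 µM nutlin-3 for 18 hours. Nutlin-3 is a small molecule that blocks the binding of MDM2 to p53; MDM2 is the ubiquitin ligase that normally marks p53 for degradation, so p53 accumulates in treated cells. 1 p53 ChIP library and 1 input library, both from treated cells, made up the samples. The series also names vehicle-treated cells, which were not analysed here, so no treated against vehicle comparison was made. The single processed table was the list of regions that the authors called in the p53 ChIP. It carries no read totals and no replicate, so the sequencing depth is unknown and no region has a replicate error. All tests below compare regions within this list, which are not replicates of the experiment.

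The question behind the list is where p53 bound the genome of these cells. The authors listed 1183 regions on hg19, of which 1159 lay on the autosomes and the X chromosome. Their median width was 258 bp (95% binomial interval of the median 247 to 272), with quartiles of 173 and 490 bp. The enrichment that the peak caller gave each region, a ratio, had a median of 50.8 (interval 50.7 to 52.0) and ran from 3.68 to 2268. The enrichment reached 100 in 111 regions and 200 in 36. In 84 regions it lay from 50 to 51, with many equal values. The median and its narrow interval lie at or near this group. The median −log10 q of the peak caller was 43.0 (interval 33.8 to 43.2) and its lowest value was 6.28. These values per region are the authors' own.

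2 regions stood far above the rest of the deposited list. Any region removed before deposit is not ranked here. R-10, on chromosome 6 from 36643833 to 36644835 with its summit at 36644258, had an enrichment of 2268, which was 44.7 times the median of the list, and a −log10 q of 26055. R-11, on chromosome 2 from 33141126 to 33141823, had an enrichment of 2154 and a −log10 q of 33287. The third, R-22 on chromosome 12 from 88953182 to 88954194, reached 723, so R-10 exceeded it 3.14-fold. R-16 on chromosome 5 from 110829220 to 110831285 followed with 519, and was the widest of the strongest 15 at 2066 bp. R-36 on chromosome 1 from 212769589 to 212770437 had 496, R-46 on chromosome 13 from 48640349 to 48641439 had 443, and R-24 on chromosome 8 from 50022755 to 50023741 had 442. R-27, a second region of chromosome 8, from 29627712 to 29628384, had 438. The 7 others among the strongest 15 were R-57 on chromosome 21, R-65 on chromosome 6, R-33 on chromosome 12, R-77 on chromosome 8, R-56 on chromosome 1, R-29 on chromosome 4 and R-70 on chromosome 16, with enrichments from 371 down to 302. The strongest 15 lay on 10 chromosomes, had a median width of 811 bp, and all had a −log10 q of at least 1142. No hg19 annotation or sequence was used here, so the genes, exons and p53 sequence motifs at these regions are not given.

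R-10, R-46, R-24 and R-16 had weaker companions within 100 kb. R-10 was followed by R-524 on chromosome 6 from 36644955 to 36645484, with its summit 931 bp away, an enrichment of 17.1 and a −log10 q of 333. R-2615, on chromosome 6 from 36645593 to 36645830, had its summit 1421 bp from that of R-10 and an enrichment of 19.7. R-241 lay 5823 bp from R-46 on chromosome 13, with an enrichment of 95.5. R-179 lay 61436 bp from R-24 on chromosome 8, with an enrichment of 200.1. R-1527 lay 23164 bp from R-16 on chromosome 5, with an enrichment of 50.7. R-11, R-22 and the remaining regions among the strongest 15 had no listed neighbour within 100 kb.

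Ranking by −log10 q instead of enrichment kept 9 of the strongest 15 regions. Of the 6 that entered, the foremost was R-7, the only mitochondrial region, which spanned positions 1 to 5138 of that genome. R-7 had the highest −log10 q of the list, 178332, which was 5.36 times that of R-11, and an enrichment of only 6.07, lower than all but 8 regions. The 5 others were R-35 on chromosome 16 from 20876986 to 20877857 with an enrichment of 145, R-30 on chromosome 4 from 78265109 to 78265534 with 242, R-58 on chromosome 19 from 6577201 to 6578131 with 96.5, R-55 on chromosome 1 from 111756852 to 111757734 with 237 and R-119 on chromosome 1 from 181103745 to 181104679 with 210. Across all 1183 regions, Spearman's rho between enrichment and −log10 q was 0.31. It was 0.42 over the 1008 regions outside the clusters described next and −0.03 over the 151 inside them. Wider regions had a higher −log10 q (rho 0.76), while width and enrichment were only weakly related over the whole list (rho 0.16). Among the 591 regions with the higher enrichment both relations of enrichment were closer, with a rho of 0.70 to −log10 q and 0.42 to width. These correlations run across regions of 1 list, which are not independent replicates.

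**Figure D1:**
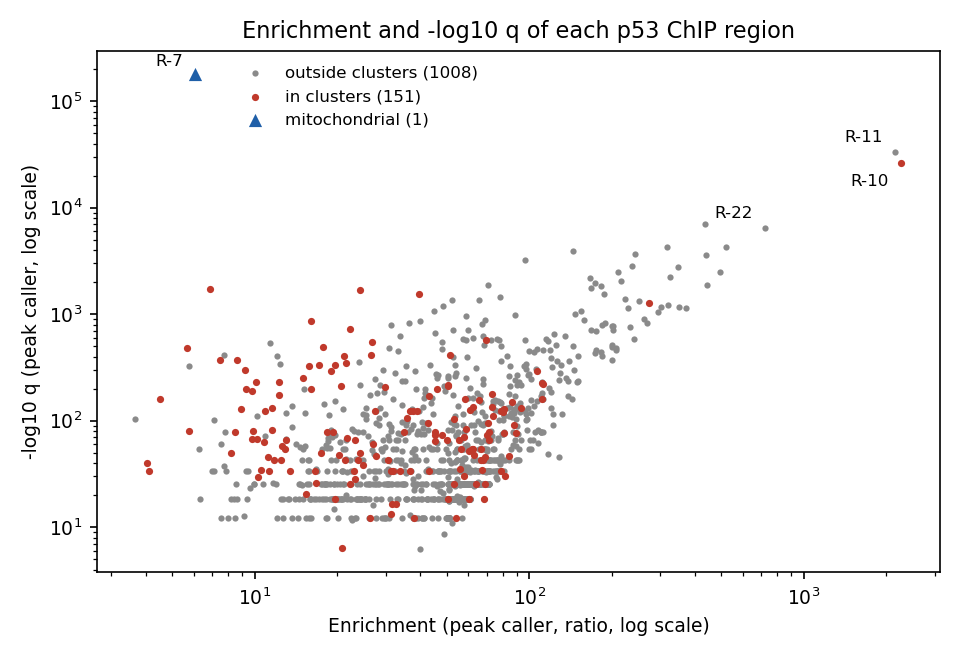
Enrichment (x axis, ratio given by the peak caller, log scale) and −log10 q (y axis, log scale) of each region of the p53 ChIP, 1 point per region, with regions in clusters in red, other regions in grey and the mitochondrial region R-7 as a blue triangle; the Y chromosome is not drawn. R-10 and R-11 lie alone at enrichments of 2268 and 2154, and R-7 combines the highest −log10 q with an enrichment of 6.07.

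Part of the regions was grouped tightly at a small number of loci. Of the 1159 regions on the autosomes and X, 151 (13.03%, exact 95% interval 11.1% to 15.1%) lay in 26 clusters, defined as runs of at least 3 regions whose neighbouring summits were within 100 kb. Evenly random placement between the first and last summit of each chromosome put 6.36 regions in clusters on average and at most 27 in 10000 placements (n = 1159 regions, one-sided p = 1e-04, the smallest these placements can give). Assembly gaps were not left out of the random placement. No hg19 annotation was used, so the position of the clusters relative to centromeres and repeats is not given. Among only the 579 regions with the higher enrichment, 31 (5.35%, exact 95% interval 3.67% to 7.51%) lay in clusters, against 0.74 on average at random. The largest cluster held 14 regions on chromosome 16 between 46389151 and 46455074. The next held 12 regions on chromosome 21 between 10714825 and 10838356, 11 on chromosome 10 between 38775807 and 38888506, and 10 on chromosome 7 within 8.66 kb, between 57546638 and 57555294. Chromosome 4 held 9 regions between 49093864 and 49125853 and 6 more between 49633931 and 49652843. Chromosome 16 had 8 further regions between 33867879 and 33899240, and chromosome 10 had 7 between 42527673 and 42665759. R-10 and its 2 near neighbours formed 1 of the smallest clusters, with 3 regions, which became 1 region when summits within 1000 bp were merged. Chromosome 14 had 4 regions between 71332013 and 71391598.

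**Figure D2:**
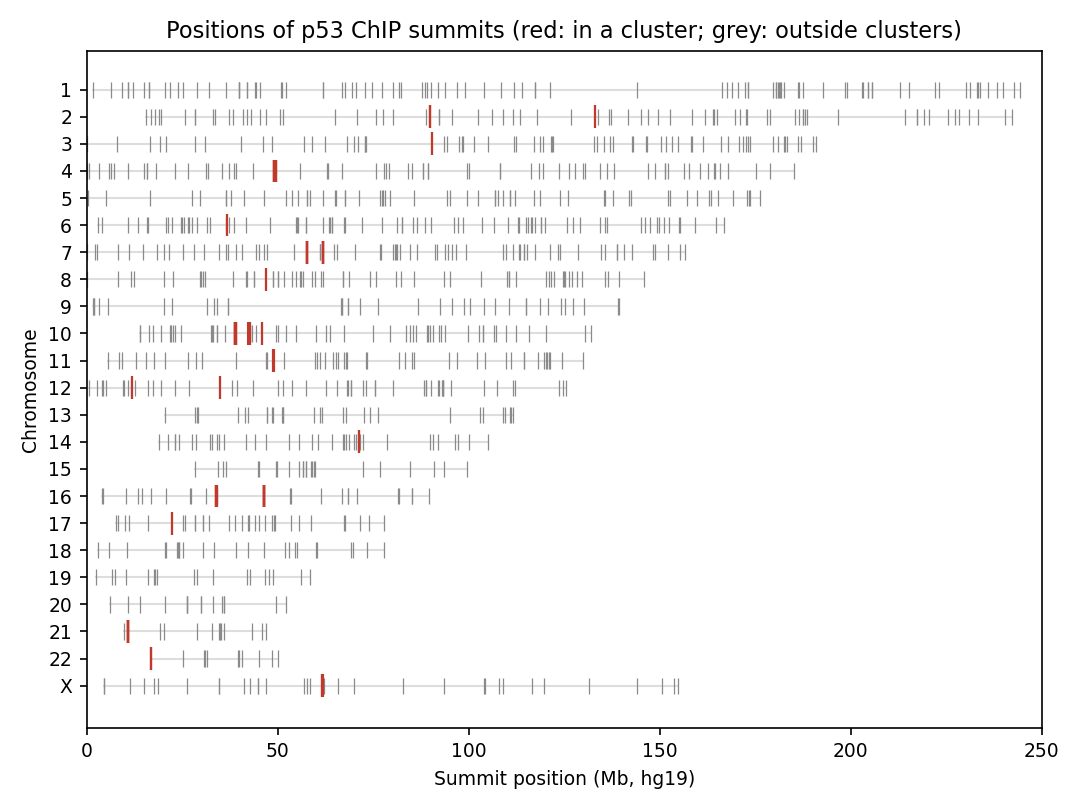
Summit positions (x axis, Mb on hg19) of the regions on each autosome and the X chromosome (y axis), 1 tick per region, with the 151 regions in clusters in red and the 1008 others in grey. The 26 clusters lie on 15 chromosomes, and chromosomes 2, 4, 7, 10, 12 and 16 each carry more than one.

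Clustered loci had a lower enrichment and were broader than the remaining regions. With each cluster counted as 1 locus, the geometric mean enrichment was 32.2 in the 26 clusters and 48.3 in the 1008 other regions, a ratio of 0.667 (95% bootstrap interval 0.569 to 0.791; adjusted p = 0.00575, two-sided permutation test of 100000 resamples, Benjamini-Hochberg over 4 comparisons). The clusters' geometric mean width was 408 bp against 282 bp, a ratio of 1.45 (interval 1.197 to 1.75; adjusted p = 0.0018 by the same permutation test). Their −log10 q was 1.63 times that of the other regions, with a bootstrap interval of 1.25 to 2.16 that excluded 1. It did not pass the same permutation test (adjusted p = 0.0501). A cluster's value is a mean over several regions, and every other value is a single region, so their spreads differ. The permutation test exchanges them as if alike, in all comparisons of clusters here. Whether −log10 q differed is therefore left undecided. 19 of the 26 clusters had a median enrichment below the 51.4 of the other regions. The lowest cluster medians were 15.7 at the chromosome 4 cluster that starts at 49093864 and 15.8 at the chromosome 7 cluster between 61968469 and 61990697. The highest was 78.7, at 3 regions of chromosome 10 between 45849839 and 45934055. Among only the 579 regions with the higher enrichment, the ratio of enrichment was 0.885 and no longer passed (p = 0.479, permutation test of 10000 resamples), with 8 clusters left. Among these regions the width ratio was 1.21 and did not pass either (p = 0.373, same permutation test).

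The density of regions differed between chromosomes, in part through the clusters. Over the length between the first and last summit, chromosome 10 had 0.720 regions per Mb (95% Poisson interval 0.575 to 0.890, counting error only), chromosome 21 had 0.618 (0.392 to 0.927) and chromosome 16 had 0.561 (0.413 to 0.743). Chromosome 9 had the lowest density of the autosomes, 0.261 (0.183 to 0.362), and X was lower, at 0.253 (0.179 to 0.347). All 23 chromosomes together had 0.407. Assembly gaps were not left out of the lengths between first and last summit. Unequal gaps could therefore contribute to the low density of chromosome 9 and to the chi-square values below. This was not tested. The chi-square per degree of freedom was 3.55 (Monte Carlo p = 1e-05, the smallest that 100000 draws can give). Counting each cluster once lowered chromosome 10 to 0.483, chromosome 21 to 0.322 and chromosome 16 to 0.292 regions per Mb. The chi-square per degree of freedom was then 1.59 (Monte Carlo p = 0.0393). Among only the 579 regions with the higher enrichment, the chi-square per degree of freedom was 1.53 and did not pass (Monte Carlo p = 0.0544).

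**Figure D3:**
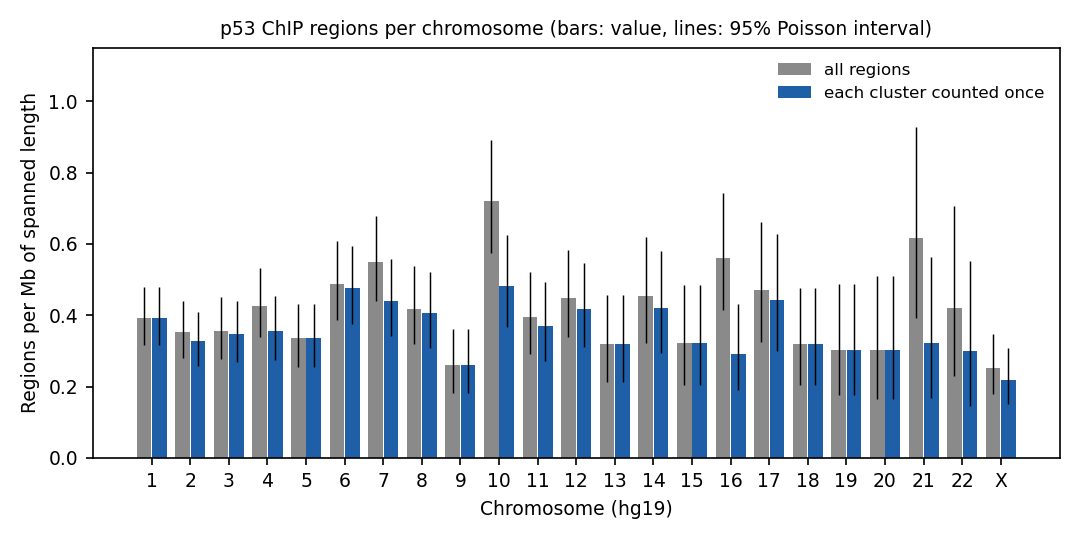
Regions per Mb of the length between the first and last summit (y axis) on each autosome and the X chromosome (x axis), with all regions in grey and each cluster counted once in blue; lines are 95% Poisson intervals. Chromosome 10 falls from 0.720 to 0.483 and chromosome 16 from 0.561 to 0.292 when clusters are counted once.

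The enrichment of many regions followed their numbering. The numbers ran from 7 to 3891, and 2702 numbers in between had no region in the list. No region had a number below 7. What the missing numbers stood for is not given in the sources used here. In 505 of 1183 regions (42.7%, exact 95% interval 39.8% to 45.6%) the enrichment was at least as high as in every region with a higher number; shuffled values gave 7.60 such regions on average and at most 17 in 1000 shuffles. 503 of these 505 enrichments were whole multiples of 0.0764 within a tolerance of 0.05 of a step. The step was the one that most enrichments of this same list matched. Chance gives such a match to 10% of values only for a step fixed beforehand. Many enrichments also repeat exactly and match together, so 10% is not an exact chance level here. Of the 678 other regions, 81 (11.9%) matched. Spearman's rho between enrichment and −log10 q was 0.82 across the 505 regions and 0.33 across the 678 others, and between enrichment and width it was 0.51 and 0.19. The 505 were picked for an enrichment that falls with number, so both contrasts follow at least in part from that selection. Between number and −log10 q, rho was alike, −0.82 in the 505 and −0.84 in the 678. The share at this upper limit was 23.2% (exact 95% interval 16.7% to 30.7%) of regions in clusters and 45.7% (42.6% to 48.9%) of the others. These intervals count each region as independent, also within a cluster. Being at the limit depends on the enrichment, which was already lower in the clusters, so the shares partly restate that pattern. Only 1 of the 519 regions with an enrichment below 50 was at the limit, and it was the last in the list. This follows from the definition. R-3886, near the end, had an enrichment of 50.02, so no earlier region below 50 could be at the limit, and the last region always is. The −log10 p values also repeated, and 509 regions (43.0%) shared 4 values.

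**Figure D4:**
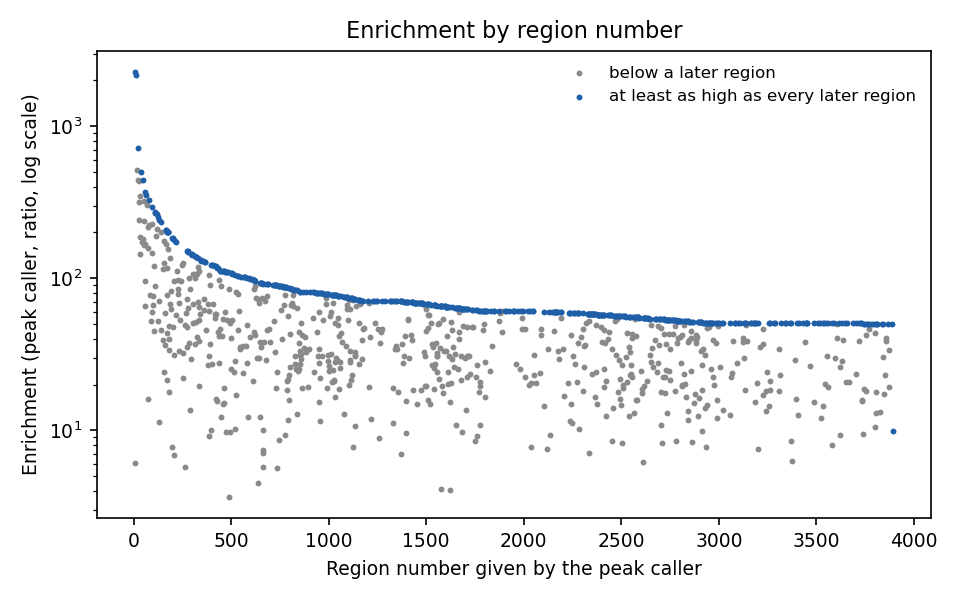
Enrichment (y axis, ratio, log scale) against the number the peak caller gave each region (x axis), with the regions at least as high as every later region in blue and the others in grey; the Y chromosome is not drawn. The blue points form an upper limit that falls, by its definition, from 2268 to just above 50. Only the last region, which is always at the limit, lies apart.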

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

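All alternatives were chosen after seeing the data, except, for the description of the list, merging summits within 200 bp and keeping only the regions of higher enrichment. No summit lay within 200 bp of another, so merging left 1183 regions, and this setting tests nothing. In the 591 regions of higher enrichment the median width was 281 bp, the median enrichment 67.6 and the median −log10 q 49.1; the rise in enrichment follows from the selection. Regions in clusters numbered 135 with neighbours within 50 kb, 172 within 200 kb, and 111 with at least 5 regions per cluster. Their share went from 13.03% down to 5.35% (31) of the 579 regions with the higher enrichment and up to 17.3% (100) of the 579 with the higher −log10 q, against 0.74 and 1.12 regions at random; the cause was not tested. The ratio of enrichment, clusters to other regions, lay between 0.465 and 0.704 and passed in 5 of 6 alternatives. Among the regions of higher enrichment it was 0.885 and did not pass; 8 clusters were left and the selection narrows the range of enrichment. The width ratio lay between 1.25 and 1.85 and passed in the same 5 alternatives, but was 1.21 among the regions of higher enrichment and did not pass. The −log10 q ratio was 1.80 and past the threshold within 50 kb (p = 0.0228, permutation test), 1.34 within 200 kb, and 1.01 (p = 0.982, permutation test) among the regions of higher enrichment; the cause was not tested. Among the regions with the higher −log10 q it was 0.878 (p = 0.662, permutation test), but this setting selects on the measure it compares and says nothing about stability. The chi-square per degree of freedom between chromosomes was 4.15 among the regions with the higher −log10 q, 1.59 with clusters counted once, and 1.53, no longer past the threshold, among those with the higher enrichment. The motif, genomic context and gene list results and their alternatives were not run, because hg19 sequence and annotation were not used here. Leaving out the largest cluster fixes the count of regions in clusters by construction, so that count is not given. No paired analysis was possible because each group has 1 library.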

Other observations

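The tests in this part were chosen after the result was seen, except the merging of summits within 1000 bp in the clusters. Away from the clusters, regions also came in pairs: 13 pairs of summits lay within 10 kb of each other, against 3.62 on average and at most 12 in 1000 random placements (n = 1008 regions, one-sided p = 0.000999, the smallest these placements can give). Within 100 kb there were 52 pairs, against 33.3 on average and at most 51 at random. 4 of the pairs lay within 1000 bp, where 1 enrichment could have been split by the peak caller. With summits within 1000 bp merged, in the list and at random alike, 9 pairs were left within 10 kb, against 3.26 on average and at most 10 at random (n = 1004 regions, one-sided p = 0.00999), and 48 within 100 kb, against 32.9 on average and at most 54 (n = 1004 regions, one-sided p = 0.00699). R-46 and R-241 on chromosome 13, 5823 bp apart with enrichments of 443 and 95.5, were the strongest pair within 10 kb by their weaker member. R-2636 and R-162 on chromosome 5 lay 5862 bp apart, with enrichments of 54.5 and 59.0.

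A fixed denominator could lie behind many of the enrichment values. If many regions shared one constant lowest control value, their enrichment would be a fixed multiple of the ChIP height and would fall on a grid of equal steps; 99.6% of the 505 regions at the upper limit did, and 11.9% of the other 678. Numbering by enrichment itself is argued against, since 57.3% of regions had an enrichment below that of a later region. A candidate explanation is that the numbers follow ChIP height, and that regions below the limit had a higher local control value. Under this hypothesis the enrichment of the 505 regions, R-10 and R-11 included, ranks ChIP height alone, and the ratio of the limit to the enrichment estimates the local control relative to its floor. No source used here states how the peak caller set its control, so this stays a hypothesis.

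The ratio of the upper limit to the enrichment in the clusters was 1.63 times that of other regions (95% bootstrap interval 1.38 to 1.93). It contains the enrichment, which was already lower in the clusters, so it mostly restates that pattern, and a control signal raised at the clusters stays open. Merging summits within 1000 bp left 24 clusters with 129 regions, against 26 with 151 before. The cluster at R-10 and 1 on chromosome 8 between 46840443 and 46851534 were not left. This merge cannot join pieces of 1 broad enrichment whose summits lie further apart. On chromosome 10, R-320 ended at 42664963 and R-1157 began at 42664969, with summits at 42663825 and 42665759. The peak caller breaking 1 broad enrichment into pieces therefore stays open for the clusters. Sequence present in more copies than the assembly holds could raise ChIP and control together there; this was not tested, because no genome sequence was used, and neither were p53 sites in tandem as a biological explanation. On the autosomes and X the ratio was highest in R-487 on chromosome 17 from 45212800 to 45213243, at 29.3, followed by R-264 on chromosome 8 from 43794457 to 43794903, at 26.0, both outside clusters.

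The mitochondrial region R-7 combined the highest −log10 q, 178332, with an enrichment of 6.07. The upper limit was 374 times its enrichment, but R-7 has the lowest number, so its limit is the highest enrichment of the list and the ratio only restates the pattern. Many copies of the molecule in ChIP and control alike is a candidate explanation that these values do not test. Binding of p53 to mitochondrial DNA was not tested either.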
